A study of Mus musculus with 6 samples.

How the data were processed

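The deposited table holds 1 log2 value per probe set and array for 6 arrays, 3 from wild-type BMSCs and 3 from BMSCs of miR-188 knockout mice, all in osteogenic medium. Per the labels' protocols, the cells were grown in 6-well plates with 10% serum, total RNA was extracted with a column kit, and biotin-labelled target was made from 6 ug of total RNA for Affymetrix arrays. The submitters' processing notes name RMA, Partek and Affymetrix Expression Console, with no version, role or order given. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set on the log2 scale, so the authors' deposited log2 values were taken as comparable between arrays. The array medians, from 7.43 to 7.50, still differed, and small changes therefore depend on how the arrays are scaled. RMA values are compressed at the dim end, so a change in a dim gene is understated. The genome build and probe annotation the authors used are not given in the sources used here, and no coordinates are printed.

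Groups were taken from the sample titles and genotype labels. Probe sets were named through GEO's annotation of the platform: of 35556 probe sets 23410 are listed and 12146 are not. Of the listed ones 21789 have 1 gene symbol, 1621 have several and 0 have none. Symbols were compared by Entrez identifier with a RefSeq gene table of assembly GRCm38.p6; 21698 of the probe sets with 1 symbol matched and 0 symbols changed. Probe sets with several symbols were given no name. For the 999 genes with several probe sets, that with the highest mean over the 6 arrays was used, which left 19938 tested genes with no filter on dim values. Levels of different genes come from different probes and were not compared with each other, except that the 95th percentile (6.72) and median (4.88) of 1194 olfactory and vomeronasal receptor genes serve as a rough guide to the level of genes that are not expressed; this guide was chosen after the data were seen.

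Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, KO188 minus WT), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All 6 arrays entered the fit with no covariate. Gene lists were tested as sets with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 28 lists of at least 3 tested genes. Of these, 8 were called, and with an estimated correlation only the interferon list was. With an estimated correlation camera also takes its degrees of freedom from the 6 arrays and not from the number of genes, which weakens the test. A call lost under it can therefore come from correlated genes, from the fewer degrees of freedom or from both. The fry test, which asks whether the genes of a set move on balance in 1 direction and does not compare the set with other genes, called 16. The balance of the osteoblast and adipocyte lists was compared with a two-sided exact permutation test over 20 assignments, whose smallest p is 0.10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

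The lists (561 entries, of which 520 were measured) were fixed before the data were examined, from general knowledge. They cover osteoblasts, adipocytes, the miR-188 locus, the study's targets, class II deacetylases, mTOR complexes, cartilage, stromal progenitors, smooth muscle, matrix, cell cycle, senescence, Wnt, BMP and TGF-beta, glycolysis and hypoxia, the respiratory chain, sterol synthesis, interferon, inflammation, the unfolded protein response, immediate early genes and glucocorticoid response. Further lists hold markers of macrophages, osteoclasts, granulocytes, lymphocytes, erythroid and megakaryocyte cells, mast cells with basophils and eosinophils, and endothelium, and sex-linked genes as a check. The annotation used here names no single-gene probe set for 41 entries, among them Runx2, Bglap and Spp1 of the osteoblast list, which were not analysed here. The list of the miR-188 locus had 1 of 6 measured members past the test and was not called by camera (adjusted p = 0.92).

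The rule for named genes, also fixed beforehand, takes every measured gene of the miR-188 locus and the study's targets. It adds the 10 genes with the largest rise and the 10 with the largest fall past the threshold with no overlap between groups, skipping predicted genes and chemosensory receptors; 2 were skipped, Gm12250 and Gm4951. It further takes the 4 members with the lowest p of the osteoblast and adipocyte lists, and up to 3 of every other list with a call. Genes named because a count was 5 or fewer, and the families in the closing section, were chosen after their values were seen.

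The tests were tried on simulated arrays of 19938 genes with the spread of this comparison. Of 50 genes each shifted by 0.15, 0.3, 0.6 and 1.2 on the log2 scale, limma found 18%, 72%, 82% and 100%, and 3 of 139 calls were false. No other genes were shifted, whereas 29.8% of tested genes were called in the data, so these shares do not carry over to the data. The camera test found a shifted list of 25 genes and called 0 of 20 unshifted ones. Noise was drawn separately for each gene, so this trial does not cover lists of correlated genes.

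Alternatives fixed beforehand were a mean-variance trend, a robust prior, median centring, quantile normalization, leaving out genes below the 25th or 50th percentile, the mean of a gene's probe sets, every probe set on its own, array weights, the replicate number as a block, leaving out each array, other thresholds, an estimated correlation, fry and a score of z-scored genes. A 2-fold threshold, camera on ranks and leaving out genes tied within a group were added after the data were seen. The ties were found in 5285 genes with identical values on at least 2 arrays of a group. A planned test of miR-188 seed sites in 3' untranslated regions was not run because transcript sequences were not used here. A planned window of 20 tested genes on each side of Mir188 on the X chromosome held only 15 on 1 side, since Mir188 lies near the start of the chromosome's tested genes. The window was therefore set to 15 and 20 genes, without Mir188 itself, after a first version, which was shifted to 1 side and included Mir188, had been looked at; the closing section gives both shares. A test of adipocyte transcripts was at 1 point reworded after its outcome had been seen and then put back to its first wording, whose result is the one given.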

Results

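Messenger RNA was profiled in bone marrow stromal cells (BMSCs), the adherent marrow cells that can become osteoblasts or adipocytes. The cells came from wild-type mice (WT, 3 arrays) and from mice lacking the microRNA miR-188 (KO188, 3 arrays), all on the C57BL/6 background and 6 months old. They were kept in osteogenic medium with 100 nM dexamethasone, 10 mM beta-glycerophosphate and 0.05 mM ascorbate-2-phosphate, which drives bone matrix formation and mineral deposition. Each RNA sample was read on 1 Affymetrix array with 35556 probe sets. The array medians lay between 7.43 and 7.50 on the log2 scale. The arrays of a group correlated at r = 0.9988 to 0.9993 across the tested genes, and arrays of different groups at 0.9909 to 0.9912. Genes are not independent replicates. The labels call the samples biological replicates without saying whether each came from its own mouse or culture. The p-values therefore measure only the spread between these samples, with a median SD per gene of 0.039 in WT and 0.048 in KO188. If the samples of a group shared material, the spread between mice was not measured. The number of arrays limits the precision. No label names a batch or culture day that holds both groups. For every gene, genotype and a culture or batch difference shared by the KO188 samples therefore cannot be told apart.

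The targeted locus was read first. Mir188, the microRNA gene that was knocked out, had a probe set level of 7.15 ± 0.01 (SD, n = 3) in WT and 7.08 ± 0.05 (n = 3) in KO188, a log2 change of -0.06 (SE 0.034, limma adjusted p = 0.24). This difference did not pass the test on the deposited values. With each array centred on its median it was -0.11 (adjusted p = 0.040), with quantile normalization it was -0.10 (adjusted p = 0.029), and over 16 alternatives the adjusted p ran from 0.029 to 0.41. The probe set lay at the 37.6th percentile of tested genes, and which part of the locus it reads or which part was deleted is not given in the sources used here, so it neither checks nor contradicts the genotype labels. Of the microRNA genes of the same X-linked cluster, Mir501 (0.12), Mir500 (0.09), Mir532 (0.02) and Mir362 (0.01) did not pass the test either. Clcn5, the chloride channel gene that hosts the cluster, fell by 0.10 (SE 0.029, adjusted p = 0.033), a call that was lost without WT replicate 1 (adjusted p = 0.10), WT replicate 3 (0.091), KO188 replicate 2 (0.065) or KO188 replicate 3 (0.088), and with every probe set tested on its own (0.056).

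The study is known to have followed Hdac9, a class II histone deacetylase gene, and Rictor, the defining subunit of mTOR complex 2, as direct targets of miR-188. Rictor was higher in KO188, at 10.61 ± 0.02 (SD, n = 3) against 10.51 ± 0.02 in WT, a log2 change of 0.09 (SE 0.026, adjusted p = 0.038). The Rictor call ended with median centring (0.05, adjusted p = 0.31) and without each of 5 of the 6 arrays, where only the fit without WT replicate 3 kept it (adjusted p = 0.046 to 0.11 over the 6), and with every probe set tested on its own (0.059). Hdac9 was 6.39 ± 0.04 in WT and 6.45 ± 0.04 in KO188 (log2 change 0.06, SE 0.036, adjusted p = 0.26) and did not pass, at a level below the 95th percentile of olfactory and vomeronasal receptor genes (6.72), which these cells are not known to use. Since the study picked these 2 genes, they are not independent evidence of a direction; adjusted over the list alone, 1 of 2 passed. Among the 6 class II deacetylase genes measured, 1 fell, Hdac6 (-0.10, adjusted p = 0.041, lost in each of the 6 fits with an array left out and with every probe set tested on its own), and 0 passed adjusted over the list alone; Hdac4 did not pass on the probe set used (0.09, adjusted p = 0.11), while its other probe set did among all probe sets (0.16, adjusted p = 0.012). Of the 13 measured genes of the mTOR complexes, 4 rose and 1 fell, and 5 passed adjusted over the list alone. Prr5l, which encodes a partner of mTOR complex 2, rose by 0.68, Deptor, an mTOR inhibitor gene, rose by 0.28, and the kinase gene Akt1 fell by 0.21. The camera test called neither list (adjusted p = 0.80 for the deacetylases and 0.54 for the mTOR complexes).

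**Figure D1:**
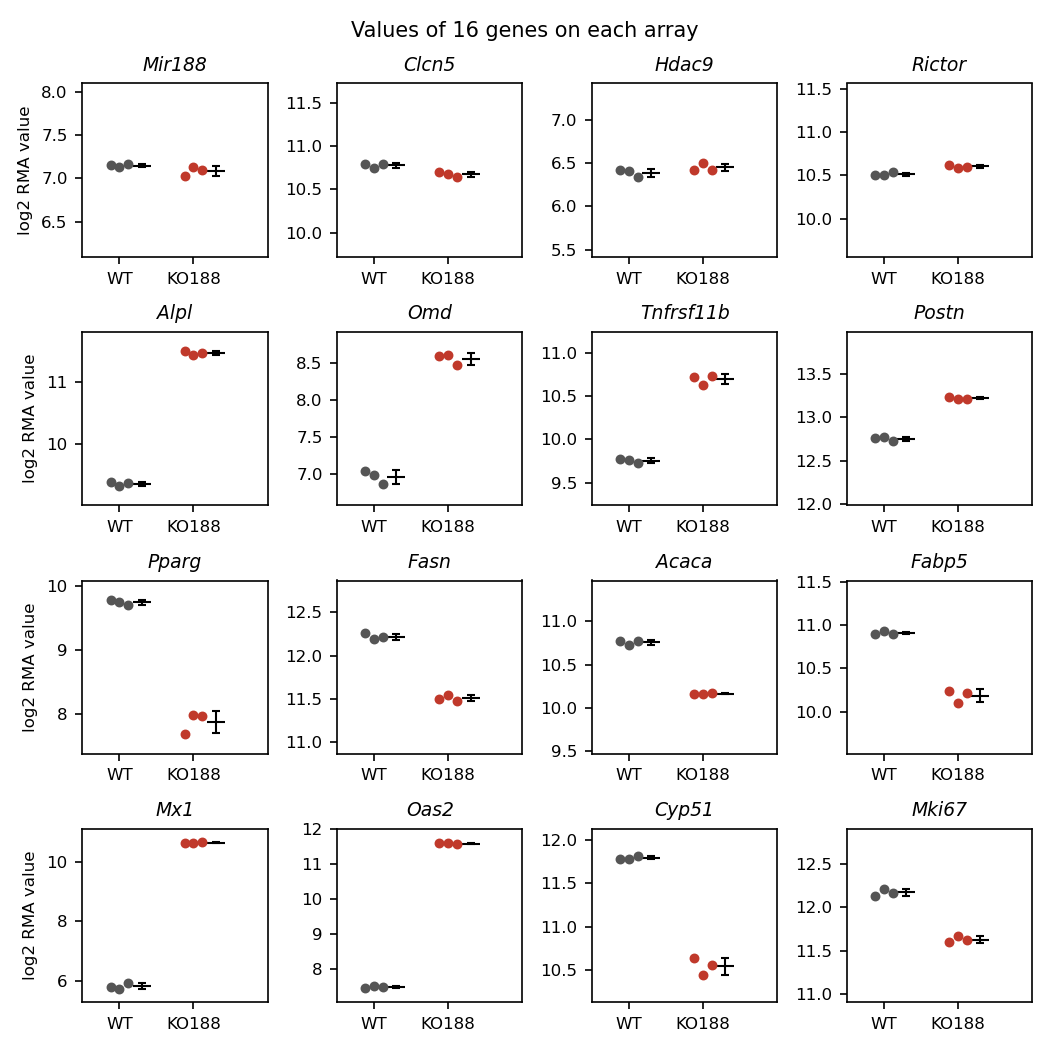
Log2 RMA values of 16 genes on each of the 6 arrays; points are arrays of WT (grey) and KO188 (red), and the black bar and whiskers beside them are the mean and SD of 3 arrays, on vertical axes that span at least 2 log2 units but begin above 0. The 2 groups of points of Mir188 overlap, with means of 7.15 and 7.08, while Alpl, Pparg and Mx1 separate by 2.08, -1.86 and 4.82.

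Genes of the osteoblast lineage were mostly higher in KO188 where they passed the test. Of 27 measured members of the osteoblast list, 11 rose, 3 fell and 13 did not pass (15 passed adjusted over the list alone). Alpl, the alkaline phosphatase gene needed for mineral deposition, rose 4.23-fold, from 9.37 ± 0.03 to 11.45 ± 0.03 (SD, n = 3 each; log2 change 2.08, SE 0.031, limma adjusted p = 8.6e-08). Omd, which encodes the bone matrix proteoglycan osteomodulin, rose 3.02-fold, Tnfrsf11b, the gene of the osteoclast inhibitor osteoprotegerin, rose 1.92-fold, and Postn, a matrix protein gene of the periosteum, rose 1.38-fold. The 3 that fell were Ank (-0.34), a pyrophosphate transporter gene, Phex (-0.16) and Lox (-0.10). The list median was 0.05 and the mean 0.31, so that a few members carried the shift. The median ran from 0.0045 with median centring to 0.14 with the dimmer genes left out, and was 0.02 without KO188 replicate 3 and 0.08 without KO188 replicate 1. The camera test called the list higher (adjusted p = 0.017), with adjusted p = 0.24 with an estimated correlation and 0.094 on ranks.

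Several adipogenic and lipid synthesis genes were lower in KO188, while most of the adipocyte list did not pass. Of 32 measured members 9 fell, 2 rose and 21 did not pass (13 passed adjusted over the list alone). Pparg, the master transcription factor gene of fat cell formation, fell from 9.74 ± 0.04 to 7.88 ± 0.17 (SD, n = 3 each; log2 change -1.86, SE 0.083, limma adjusted p = 1.5e-05). Fabp5, a fatty acid binding protein gene, fell by 0.72, Fasn (fatty acid synthase) fell by 0.71 and Acaca (acetyl-CoA carboxylase) fell by 0.59. The 2 that rose were Lpl (0.54), the lipoprotein lipase gene, and Klf15 (0.20). The list median was -0.03 and the mean -0.14, and the camera test did not call it (adjusted p = 0.15; 0.47 with an estimated correlation), though with every probe set tested on its own it did (adjusted p = 0.016).

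The series title names a switch between these fates, and the balance was read as 1 value per array, the mean centred log2 value of the osteoblast list minus that of the adipocyte list. It was -0.23 ± 0.02 (SD, n = 3) in WT and 0.23 ± 0.02 (n = 3) in KO188, a difference of 0.46. All 3 KO188 arrays lay above all 3 WT arrays (two-sided exact permutation p = 0.10, the smallest that 3 against 3 arrays can give).

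Interferon-stimulated genes showed the largest differences between the groups. All 21 measured members of the interferon list rose in KO188, by 1.01 to 4.82 on the log2 scale with a median of 2.39 (5.25-fold), and all 21 passed adjusted over the list alone. Mx1 and Mx2, which encode antiviral GTPases, rose 28.3-fold and 13.4-fold, Oas2, a double-stranded RNA sensing enzyme gene, rose 17.2-fold, and Gbp3, a guanylate-binding protein gene, rose 8.10-fold. The WT levels of Mx1 (5.83) and Mx2 (6.62), like those of Ifi213 (6.06), Ifi206 (6.28) and Gbp4 (6.53), lay under the receptor guide of 6.72, so their folds and their order by fold are inexact. WT cells also held several of these transcripts at high levels, such as Gbp3 at 9.13 ± 0.03 (SD, n = 3). The camera test called the list higher (adjusted p = 1.7e-31), and the call held with an estimated correlation (adjusted p = 0.0084). Of the 10 named genes with the largest rise over all tested genes, Ifi213 (42.1-fold), Ifi206, Ifit3b, Gbp4, Iigp1 and Cxcl9 (12.4-fold) belong, from general knowledge, to interferon-induced families, beside Mx1, Mx2 and Oas2 of the list. The tenth, Aspn, which encodes the matrix proteoglycan asporin, rose 15.5-fold. Ifi213, Ifi206, Ifit3b and Gbp4 have near-identical relatives, so their signal can be shared between copies. Markers of immune cells moved little beside them: in the 3 lists of macrophage, granulocyte and lymphocyte markers, 2 of 57 members rose and 0 fell, with a median change of 0.00. Of the 57, 39 had 6-array means at or below the receptor guide, where changes are compressed.

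Sterol synthesis genes fell together. All 18 measured members of the sterol list were lower in KO188 and passed over all genes and adjusted over the list alone, with changes from -1.25 to -0.36 and a median of -0.70. Cyp51, a sterol demethylase gene, fell by 1.25, Msmo1 fell by 0.95, Mvd, of the mevalonate pathway, fell by 0.92, and Insig1, a sensor of sterol load, fell by 0.73. The camera test called the list lower (adjusted p = 1.0e-15), with adjusted p = 0.19 with an estimated correlation. That correlation was 0.21, and the run, which has fewer degrees of freedom, gave an unadjusted camera p of 0.014.

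Proliferation genes were lower in KO188. Of 28 measured members of the cell cycle list 23 fell, 1 rose (Ccne1, 0.33) and 4 did not pass, with 24 passing adjusted over the list alone and a median of -0.26. Mki67, the gene of the Ki-67 proliferation antigen, fell by 0.54, Rrm2, a ribonucleotide reductase gene, fell by 0.52, and the spindle checkpoint gene Bub1 fell by 0.38. The camera test called the list lower (adjusted p = 3.6e-10), with adjusted p = 0.24 with an estimated correlation. Nuclear genes of the respiratory chain also fell in 14 of 23 measured members (14 adjusted over the list alone, 0 rose), with a median of -0.13 (adjusted p = 3.5e-04; adjusted p = 0.42 with an estimated correlation). Ndufb5 fell by 0.33, Atp5a1 fell by 0.24 and Cox5a fell by 0.22. On the list of glycolysis and hypoxia genes 9 of 19 fell and 1 rose, Adm (0.61), with 12 passing adjusted over the list alone; Egln3, an oxygen sensor gene, fell by 0.93 and Ndrg1 fell by 0.53. Its camera call (adjusted p = 0.024) was adjusted p = 0.24 with an estimated correlation, and it ended with median centring (0.052), quantile normalization (0.33), genes below the 50th percentile left out (0.061), the mean of a gene's probe sets (0.055), tied genes left out (0.057) and KO188 replicate 2 left out (0.055).

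Of 26 measured Wnt pathway genes 11 rose and 2 fell (14 passed adjusted over the list alone; median 0.09). Those with the lowest p were not all activators: Ccn5, the gene of a secreted matrix protein, rose 3.53-fold, Rspo2, an enhancer of Wnt signalling, rose 2.37-fold, and Sfrp2, which encodes a secreted Wnt-binding protein, rose 2.34-fold, while Ccn4 (-0.51) and Lef1 (-0.28) fell. The camera call (adjusted p = 0.012) was adjusted p = 0.51 with an estimated correlation, and it also ended when genes tied within a group were left out (0.095). The median of the Wnt list ran from 0.03 to 0.15 over all alternatives and from 0.05 to 0.10 with 1 array left out. Glucocorticoid-induced genes, read because the medium of both groups held dexamethasone, rose in 9 of 16 measured members and fell in 2, Glul (-0.38) and Angptl4 (-0.33), with 12 passing adjusted over the list alone and a median of 0.15. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose 1.76-fold, Pdk4 rose 1.47-fold and the phosphatase gene Dusp1 rose 1.42-fold (camera adjusted p = 0.010; adjusted p = 0.47 with an estimated correlation).

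The remaining lists were not called by camera. Stromal progenitor genes rose in 7 and fell in 4 of 17 members (11 adjusted over the list alone): Pdgfra, a growth factor receptor gene, rose 1.82-fold, whereas Mcam (-1.24) and Nes (-1.12), markers of perivascular stromal cells, fell; the median was 0.04 and the mean -0.07. Smooth muscle genes rose in 4 and fell in 6 of 14 (11 adjusted over the list alone), with Cnn1 (-0.73) and Tagln (-0.42) lower and Mylk (0.35) higher. Matrix genes rose in 8 and fell in 7 of 24 (16 adjusted over the list alone), led by the collagen-binding proteoglycan gene Fmod (6.27-fold higher), Col6a2 (0.68) and Thbs2 (0.39); the median was 0.00 and the mean 0.11. BMP and TGF-beta genes rose in 9 and fell in 9 of 29 (19 adjusted over the list alone), with Tgfb3 (0.62) and Tgfb2 (0.38) higher and Id2 (-1.12), a BMP-responsive gene, lower; the median was 0.02 and the mean -0.05. Senescence-linked genes rose in 7 and fell in 3 of 16 (11 adjusted over the list alone), inflammation genes rose in 6 and fell in 4 of 21 (11), immediate early genes rose in 9 and fell in 3 of 19 (14), and unfolded protein response genes rose in 4 and fell in 7 of 18 (13; median -0.06, mean 0.01). Named members of these lists were the cytokine gene Il6 (1.01), Il1rn (1.90), which encodes an interleukin-1 antagonist, Saa3 (0.43), Cdkn2b (0.47), Lmnb1 (-0.47), Zfp36 (0.54), Atf3 (0.51), Ddit3 (0.47) and Sesn2 (0.35). Cartilage genes rose in 2 of 18, Sox9 (0.52) and Sox5 (0.19), with 1 passing adjusted over the list alone; the Sox5 call was lost with median centring (adjusted p = 0.062), quantile normalization (0.076) and every probe set tested on its own (0.056), and without WT replicate 1 or 2 or KO188 replicate 1 or 2 (0.074 to 0.091).

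Markers of other marrow cells showed few calls. Macrophage markers rose in 1 of 24 members (Mpeg1, 1.32) with a median of -0.02, and Cd14 (-0.27, adjusted p = 0.060) did not pass. Cd14 did pass limma's test in 7 of 16 alternatives, with adjusted p from 0.024 to 0.19 over the 16. Granulocyte markers rose in 1 of 17 (Lcn2, 0.41), and of 16 lymphocyte markers 0 passed limma's test over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05). Osteoclast markers rose in 3 of 15, Tcirg1 (1.05), Ctsk (0.88) and Clcn7 (0.35), which serve acid secretion and matrix breakdown; the other 12 did not pass. Of 11 erythroid and megakaryocyte markers 2 fell, the platelet chemokine gene Ppbp (-1.06) and the transferrin receptor gene Tfrc (-0.88), which dividing cells also use. Of 14 mast cell, basophil and eosinophil markers Hdc rose by 0.58 and Mcpt8 fell by 0.97. The KO188 level of Mcpt8 (6.15) lay under the receptor guide, so the size of its fall is inexact. Of 15 endothelial markers Kdr rose by 0.24 (adjusted p = 0.021), a call lost without any 1 of the 3 WT arrays or without KO188 replicate 1 (adjusted p = 0.051 to 0.079). Kdr lay under the receptor guide in both groups (6.40 in WT, 6.63 in KO188), so the size of its rise is inexact. Adjusted over each list alone, 1 macrophage, 1 granulocyte, 3 osteoclast, 2 erythroid or megakaryocyte, 2 mast cell group and 0 endothelial markers passed.

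**Figure D2:**
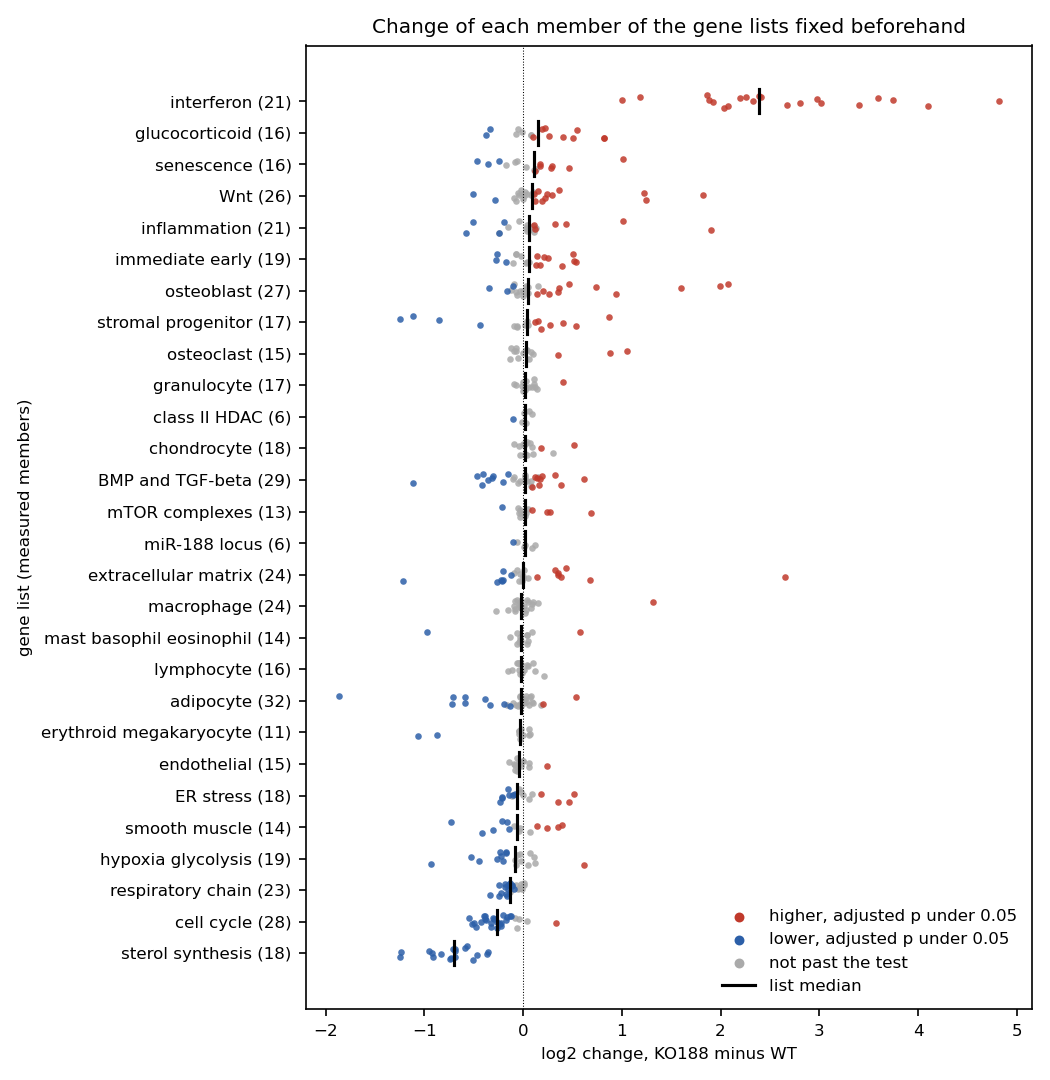
Log2 change (KO188 minus WT) of each measured member of the 28 gene lists tested as sets, 1 row per list ordered by its median (black bar), with the number of measured members in brackets; vertical scatter within a row carries no value. Red and blue points passed adjusted p 0.05 as higher or lower and grey points did not; the interferon list (median 2.39) and the sterol list (median -0.70) stand at opposite ends with no grey point.

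Over all genes, 5937 of 19938 passed limma's test at an adjusted p of 0.05, or 29.8%, of which 2643 were higher and 3294 lower in KO188. With each array centred on its median, 2007 were higher and 4505 lower, so the share of higher calls was 30.8% in place of 44.5%. Most changes were small, with a median absolute log2 change of 0.23 among the genes called; 611 of them changed at least 1.5-fold (440 higher, 171 lower) and 243 at least 2-fold (219 higher, 24 lower). In 41.5% of all tested genes the 3 KO188 values did not overlap the 3 WT values, against 10% by chance. The 10 named genes with the largest fall included, besides Pparg and Cyp51, Akr1c18, a progesterone-metabolising enzyme gene (fell by 2.05), the prolactin family gene Prl2c5 (fell by 1.87), Gpr149 (fell by 1.81), Sprr1a (fell by 1.73) and Tfdp1, the gene of an E2F partner (fell by 1.69 on 1 probe set and by 1.32 on the other). Zdhhc2 fell by 1.65, the integrin gene Itga6 fell by 1.38 and Ereg, which encodes the growth factor epiregulin, fell by 1.28. Prl2c5 has near-identical relatives that can share its signal. The KO188 levels of Akr1c18 (6.30) and Gpr149 (5.81) lay under the receptor guide of 6.72, so the sizes and order of their falls are inexact.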

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

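The tests of immune cell RNA, of a shared culture or batch difference, of adipocyte transcripts and of Xist and the Y-linked genes were chosen only after the results were seen.

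Probe sets that carry no gene name here also differed between the groups. Among 1621 probe sets paired with several genes, 150 were higher and 255 lower in KO188 past limma's adjusted threshold. Of these, 34 were at least 2-fold higher and 3 at least 2-fold lower, with changes from -1.89 to 3.28 on the log2 scale. Among 12146 probe sets with no listed gene, 749 were higher and 830 lower. Of these, 47 were at least 2-fold higher and 3 at least 2-fold lower, with changes from -1.62 to 3.43. The unnamed probe sets stood out because they lie outside the comparison of named genes, and what they read was not analysed here.

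The 5937 calls came from the real grouping; the other splits of the 6 arrays into 3 and 3 gave at most 0 calls with limma. The real split was 1 of 10 that gave as many, and 10 splits are too few for a share under 0.05. Each other split has WT and KO188 arrays on both sides, so the group difference widens its spread and few calls could arise. These splits therefore do not show what arrays without a group difference would give.

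Interferon-stimulated genes were higher in KO188 in 21 of 21 members. RNA from immune cells as the main source of this signal is argued against: the 57 macrophage, granulocyte and lymphocyte markers had a median log2 change of 0.00424 with 2 that rose, and the 18 of them whose 6-array mean lay above the receptor guide had a median of 0.01 with 1 that rose (Lcn2, 0.41). The other 39 had means at or below it, where changes are compressed; of these Lyz2 was flat (5.66 in WT, 5.57 in KO188) while the macrophage marker Mpeg1 rose from 5.72 to 7.04 in KO188, so a few immune cells, such as ones releasing interferon, are not excluded. A candidate source is interferon made in the KO188 cultures, since Ifna4 rose by 1.82 and Ifnb1 by 1.16, though both lay below the guide of 6.72 in WT (6.12 and 6.32, so the sizes are inexact), most interferon genes did not pass and near-identical copies can share signal. A culture or batch difference shared by the 3 KO188 samples, infection included, stays open because 0 labels name a batch or culture day that holds both groups, so it and the untested effect of losing miR-188 cannot be told apart.

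Adipogenic and lipid synthesis genes such as Pparg and Fasn were lower in KO188. Fewer adipocytes in the KO188 wells would lower abundant fat cell transcripts, but Adipoq, Plin1, Cidec, Cd36, Cidea and Retn had log2 changes of -0.01, -0.01, 0.00, 0.03, 0.03 and 0.08, and none passed limma's test, whereas Fabp4, another fat cell transcript, fell by 0.33 (adjusted p = 0.0061). The median WT level of these 6 was 6.3, with Plin1, Cidec and Retn above the 95th percentile of receptor genes (6.73 in WT) and the others below it. The values do not settle whether adipocytes were present in WT at all, so a difference in adipocyte number stays open, and an effect of genotype on lipid genes within stromal cells could also account for the pattern and was not tested.

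Xist and the Y-linked genes Kdm5d, Uty and Eif2s3y were low on all 6 arrays, with mean levels from 4.88 (Uty) to 5.72 (Kdm5d); at these levels the Xist change was -0.13 (limma adjusted p = 0.047) and the Y-linked genes did not pass (0.04 to 0.15). Animals of either sex should express at least 1 of the 2 kinds. Ddx3y, a further Y-linked gene of the list, had no single-gene probe set here and was not read. Probe sets that do not respond are a candidate explanation, and the highest level, 5.72, lies below the receptor guide of 6.72, which leaves silent probe sets and absent transcripts impossible to separate. No biological explanation was tested.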

How the results depend on the processing

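The tests with a 2-fold threshold, with camera on ranks and without tied genes were chosen only after the results were seen. The count of 5937 calls stayed within 1.5 times under every alternative of fit, scaling, filter and array choice, from 4835 to 5553 with 1 array left out. A fold threshold of 1.5 at an unadjusted p of 0.05 left 611 genes (440 higher, 171 lower), and a 2-fold threshold left 243 (219 higher, 24 lower), because most changes were small. With the replicate number as a replicate block, 5019 genes were called, 4837 of them shared with the fit without it; same-numbered arrays did not deviate together (r = 0.018, 0.010 and -0.03), so the numbers were not read as pairs. Among the named genes the block ended the calls of Clcn5 (adjusted p = 0.095), Rictor (0.12), Hdac6 (0.12), Sox5 (0.068) and Kdr (0.058) and added that of Col10a1 (0.020).

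The osteoblast list shift of 0.05 was no longer called by camera with an estimated correlation (median 0.0486, adjusted p = 0.24) or on ranks (median 0.0486, adjusted p = 0.094). The estimated correlation was -0.02, below the preset 0.01, so a higher correlation among the members was not the reason. The 2 camera runs otherwise differ in degrees of freedom, which an estimated correlation takes from the 6 arrays and not from the number of genes. The unadjusted camera p was 0.0042 at the preset and 0.032 with the estimate. What ended the call on ranks was not tested. The list was called in the other 16 of 18 alternatives. Its median ran from 0.0045 to 0.14 over all alternatives and from 0.02 to 0.08 with 1 array left out. The adipocyte list shift became called with every probe set on its own (median -0.0279, adjusted p = 0.016) and with fry (median -0.0260, adjusted p = 3.4e-04), which asks another question; the cause of the first was not tested. Its median ran from -0.13 to -0.01 over all alternatives and from -0.04 to -0.01 with 1 array left out. The score difference of 0.46 ran from 0.45 to 0.47 with 1 array left out. Of all list results under the alternatives, 473 kept their side of the threshold, 15 fell short of it and 9 newly passed; of the named gene results 1615 kept it, 35 fell short and 26 newly passed. No result past the threshold changed direction.

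The seed site test and its alternatives were not run. Mepe had 1 value on all 6 arrays, as did 22 genes in all, and 5285 genes had identical values within a group; without them 5502 of 14653 genes were called. Dim probe sets limit what can be seen, since a true change is compressed near background.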

Other observations

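The families described here, and the window in the test of genes beside Mir188, were chosen only after the results were seen. Antigen presentation genes of the class I pathway were higher in KO188. All 10 measured members rose, among them H2-Q4 (2.74), a class I molecule gene, the peptide transporter gene Tap1 (2.97), the immunoproteasome gene Psmb10 (1.70) and B2m (0.19), the shared light chain, which was already at 13.26 ± 0.01 (SD, n = 3) in WT. Of 6 class II genes 0 rose and 1 fell, Cd74 (-0.29). H2-Q4 has near-identical relatives. Genes of nucleic acid sensing, which include adaptors and regulators beside the sensors, rose in 10 of 11 members. Zbp1 (3.43), Dhx58 (3.36), Tlr3 (2.60) and Ifih1 (2.27) were among them, while the adaptor gene Mavs (-0.05) did not pass. Of 16 interferon genes 3 rose, Ifna4 (1.82), Ifnb1 (1.16) and Ifna14 (0.20), and of 4 interferon receptor genes 2 fell, Ifnar1 (-0.14) and Ifngr2 (-0.15). The 10 class I genes include Tap1 of the interferon list.

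Of 15 measured genes of small leucine-rich proteoglycans, which organise collagen fibrils, 8 did not pass. Another 6 rose, Aspn (3.96), Fmod (2.65), Omd (1.60), Ogn (1.28), Prelp (1.14) and Ecm2 (0.86), whereas Dcn, the decorin gene, fell by 1.22. The WT level of Ecm2 (6.13) lay under the receptor guide, so the size of its rise is inexact. Aspn and Omd both lie on chromosome 13, and whether neighbouring members rose together was not tested. The family was not tested as a set. Of 19 lysosome genes 10 rose and 4 fell, with changes of modest size such as Npc2 (0.57) and Mcoln1 (0.36), next to the osteoclast list's Tcirg1 and Ctsk. Of 5 prolactin family genes Prl2c5 fell, and the other 4 did not pass. These 4 lay below the receptor guide, where changes are compressed and a fall is harder to see.

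A local effect of the altered allele, or of sequence carried along with it, was tested as a hypothesis on the genes beside Mir188. The 35 nearest tested genes, 15 on 1 side and 20 on the other, had a median absolute log2 change of 0.09, and a share of 0.371 of the 668 other windows of that size on the X chromosome had one as large. Of the 35 genes 11 passed limma's test, or 31.4%, against 27.7% of the 739 tested X genes. The first version of the window, with 40 genes shifted to 1 side and Mir188 among them, gave a share of 0.0684. The versions differ in size, position and the use of Mir188, so the share depends on how the window is set. Which of these moved it was not tested. Neither share was under 0.05 and neither median was below that of the other windows (0.08), so a local effect stays open.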
